A study of Homo sapiens with 28 samples.

How the data were processed

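Gene expression was measured by RNA sequencing in 28 libraries of human memory T cells. The cells had been transduced with lentiviral vectors carrying the interleukin-23 receptor (IL-23R) or the interleukin-12 receptor chain IL-12Rβ2, and receptor-positive cells were isolated. Each receptor line had 7 groups of 2 libraries, which gave 14 groups. The groups were unstimulated cells, cells with the matching cytokine, cells with antibodies against CD3 and CD28, and cells with both, the last 3 at 4 h and at 20 h. Antibodies against CD3 and CD28 stand in for the T cell receptor signal and its costimulation. The sample labels give 20 h for the later time, while the series text gives 12 h, and 20 h is used here. The labels do not say whether the libraries of a group came from separate donors or separate cultures, so the p-values measure the spread between these libraries only.

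Polyadenylated RNA was made into stranded libraries and sequenced on a HiSeq instrument in 6 pools, per the labels. The deposited table from the authors holds counts per gene symbol with no further normalization, on genome build GRCh37. The aligner, the counting tool and the annotation are not given in the sources used here. Because the build of the reference tables at hand differs, no coordinates are given. Every value was whole and none was below 1. The numbers of genes at 2, 3, 4, 5 and 6 fell roughly as they would if 1 had been added to each count: the share at 3, relative to 2, was 0.565, against 0.5 for an added 1 and 0.667 for a floor that replaced lower values. The values were used as deposited, and subtracting 1 was tried as an alternative. Rounding of estimated counts could not be excluded. The table had 30373 lines, of which 27 carried only a number in place of a symbol. These held 0.19% to 0.34% of the counts and were left out, and the other 30346 were kept. Of these, 8831 were at 1 in all libraries.

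Total counts per library were between 17.2 M and 57.8 M, with a median of 30.8 M. A gene without reads could have had up to 3 counts by chance, or 0.174 CPM (counts scaled to the library total) in the shallowest library and 0.0519 in the deepest. This limit covers counting error only.

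Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16, which left 15570 genes. TMM normalization and the quasi-likelihood F test of edgeR were applied to all 28 libraries with 1 mean per group and no covariate, which left 14 residual degrees of freedom. There were 19 comparisons: each cytokine alone against unstimulated cells, each cytokine with the antibodies against the antibodies alone, the antibodies alone against unstimulated cells, the unstimulated lines against each other, the IL-23 response minus the IL-12 response, and the 20 h response minus the 4 h response. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Errors printed after ± are standard errors of the log2 change, taken from the F statistic, unless said otherwise. Each group had n = 2.

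Cytokine alone and antibodies alone could be compared only with cells at 0 h, so in those comparisons the treatment and the time in culture changed together. With the antibodies, the cytokine comparisons were matched for time.

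In every group the libraries differed from each other in a similar way. The first component of the deviations from the group means held 57.3% of the within-group variance, against 8.2% in simulated data without such a difference. A fit with the side of each library on this component as a term, with 13 residual degrees of freedom, was chosen after seeing the data. It is called the split term below, and its values are printed beside the others. A split found in the same data makes the spread look smaller than it is. In simulated counts shaped like the comparison of IL-23 with the antibodies at 20 h, with 100 genes changed 2-fold and 100 changed 4-fold, the fit without the term recovered 39% and 72%, with 0.9% false calls. The fit with the term recovered 57% and 86% with 8.9% false calls, or 14 of 157. In these counts all 28 libraries were placed on the right side. The values therefore do not show what finding the split in the data costs, and they rest on 1 simulated data set.

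Before the data were examined, 24 gene lists, the 19 comparisons, the alternatives and the rule for naming genes were fixed. The lists were Th17, inflammatory Th17, Th1, Th2, follicular helper, regulatory, resting memory, cytotoxic, inhibitory receptor, T cell activation, STAT3 target and cytokine feedback, glucocorticoid receptor, cell division, glycolysis, cholesterol synthesis, interferon-stimulated, unfolded protein response and heat shock genes, mitochondrially encoded mRNAs, and markers of B cells, myeloid cells, NK cells, CD8, γδ and MAIT cells, and T cells. Some genes stood in more than 1 list. The mitochondrial list had no measured member, so 23 lists were tested with camera of limma 3.58.1 (log2 CPM, prior count 2, preset correlation 0.01), adjusted over 437 tests. With an estimated correlation, 0 of the 107 calls held, and the smallest adjusted p was 0.0915. With fry of limma, which tests whether a list's genes move on balance one way, 60 of the 107 held, and 104 held with camera in the fit with the split term. With the split term and an estimated correlation together, 2 of the 107 held.

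Named genes were the receptor genes, the 6 largest rises and 4 largest falls per cytokine comparison and the 4 largest each way per other comparison, and members of the lists. The largest changes were taken among genes past the threshold with a mean of at least 5 CPM in the higher group and, for comparisons of 2 groups, without overlap between the libraries. Sex-linked genes, T cell receptor and immunoglobulin segments and unnamed features were not named. The rule also took transcripts known only by a sequence-record number, which are not described. Some further results are not reported here.

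The alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts (21515 genes), a fit of only the groups compared, each library left out in turn, and, chosen after seeing the data, the split term, 1 subtracted from every value and a block for the number of the column. With only the groups compared, a comparison of 2 groups had 2 residual degrees of freedom. With 1 library left out, its partner was assumed to vary like the other groups. Such a fit had no split term and left a library of only 1 side in that group. The shared difference between the sides then entered the comparison, so it can also decide whether a call is kept or lost. Genes said to hold with any one library left out were picked for this. In each comparison of a cytokine with its control, most named genes past the threshold were lost in at least 1 such fit. R 4.3.3 and Python 3.11.15 were used.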

Results

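The introduced IL-12 receptor chain was visible in the counts, and the introduced IL-23 receptor was not. IL12RB2, which encodes the signalling chain of the IL-12 receptor, held 1.25% to 2.88% of all counts in the 14 libraries of IL-12Rβ2 cells and at most 0.013% in the 14 libraries of IL-23R cells. In unstimulated cells the log2 difference, IL-23R minus IL-12Rβ2, was -9.82 ± 0.64, adjusted p = 2.66e-07 (n = 2 per group; -9.70 ± 0.49 with the split term). IL23R, which encodes the chain specific for IL-23, was between 0.422 and 4.22 CPM in IL-23R cells and between 0.518 and 7.67 in IL-12Rβ2 cells. Each library held 9 or more counts of IL23R, which is above the limit of 3 counts. In the same unstimulated cells IL23R did not pass the threshold (-0.27 ± 0.53, adjusted p = 0.942; -0.23 ± 0.53, adjusted p = 0.866 with the split term). With antibodies against CD3 and CD28, against 0 h, IL23R rose in IL-23R cells by 1.96 ± 0.51 at 4 h and 2.82 ± 0.51 at 20 h, and in IL-12Rβ2 cells by 2.47 ± 0.51 at 20 h. These calls held with any one library left out. With time matched, as described below, IL23R passed at 20 h in both lines (2.47 ± 0.51 and 2.92 ± 0.50) and not at 4 h in IL-23R cells (0.31 ± 0.49, adjusted p = 0.668).

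**Figure D1:**
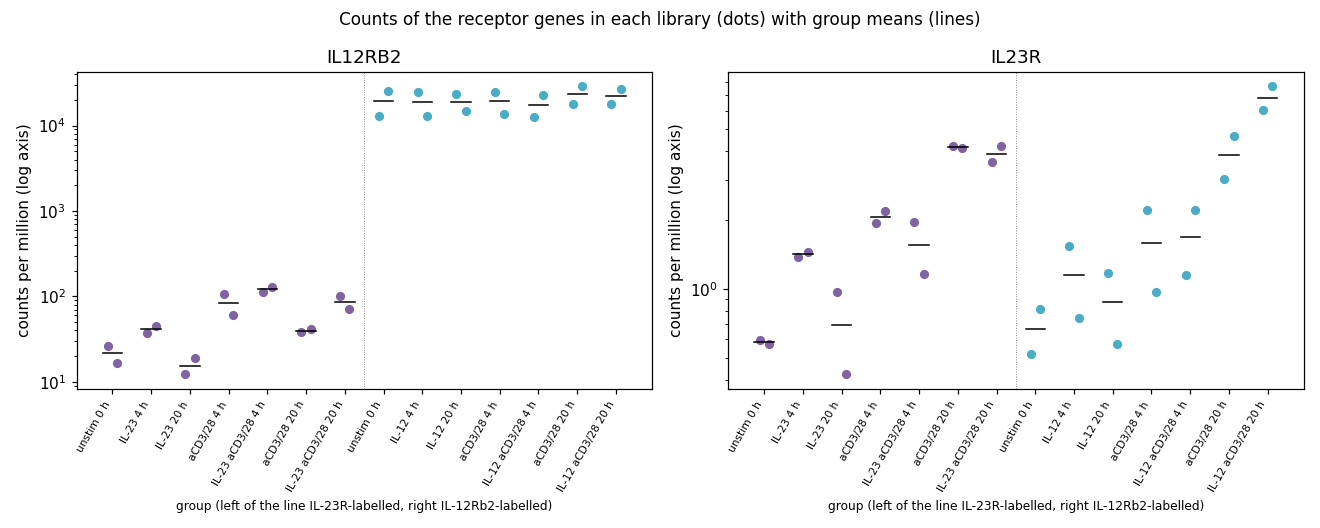
CPM of the 2 receptor genes in each library, by group. Each point is 1 library.

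The libraries of each group differed in a shared way. After orienting, all 91 pairs of groups had a positive correlation of their within-group differences, with a lowest value of 0.38. Of the 15570 genes, 159 were fully separated between the sides over all 28 libraries. The sides were found from the same values, so part of this follows from the choice. Of these, 47 were higher on one side and 112 on the other, and 3 had 10 counts or fewer in all libraries of one side and 100 or more in all of the other. Total counts did not differ between the sides (log2 0.04, exact sign-flip p = 0.826, n = 14 pairs). Normalization factors were between 0.883 and 1.08.

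Before stimulation, IL-23R cells had less SOCS3, a feedback inhibitor of cytokine signalling, than IL-12Rβ2 cells (-1.82 ± 0.18, adjusted p = 0.000113, n = 2 per group; -1.82 ± 0.18 with the split term). GPI, an enzyme of glycolysis, was also lower (-0.79 ± 0.11, adjusted p = 0.00647; -0.79 ± 0.10 with the split term), and so was MEOX1, a homeobox transcription factor outside the naming rule and chosen after seeing the data (-2.76 ± 0.39, adjusted p = 0.00647; -2.82 ± 0.35 with the split term). GPI was lost without the filter on low counts (adjusted p = 0.27) and with only the groups compared (0.805). With IL12RB2, these were the 4 genes past the threshold, all lower in IL-23R cells, against 83 higher and 269 lower with the split term. Leaving out library 2 of either line left 2 genes, IL12RB2 and SOCS3, and leaving out library 1 of IL-12Rβ2 cells left these and GPI. MEOX1 was lost with any one library left out (adjusted p up to 0.115). By list, cell division genes (median log2 -0.36, camera adjusted p = 1.16e-11, adjusted p = 0.152 with an estimated correlation), glycolysis genes (median log2 -0.50, camera adjusted p = 1.22e-06, adjusted p = 0.448 with an estimated correlation) and STAT3 target genes (median log2 -0.48, camera adjusted p = 8.58e-05, adjusted p = 0.165 with an estimated correlation) were lower. Interferon-stimulated genes (median log2 -0.28, camera adjusted p = 0.0103, adjusted p = 0.578 with an estimated correlation) and cholesterol synthesis genes (median log2 -0.17, camera adjusted p = 0.0266, adjusted p = 0.752 with an estimated correlation) were also lower. Inflammatory Th17 genes (median log2 0.24, camera adjusted p = 0.0251, adjusted p = 0.617 with an estimated correlation) and the CD8, γδ and MAIT markers (median log2 0.37, camera adjusted p = 0.0353, adjusted p = 0.198 with an estimated correlation) were higher.

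More genes passed the threshold with stimulation through CD3 and CD28 than with either cytokine. At 4 h the costimulatory receptor gene TNFRSF9 rose by 7.60 ± 0.76 in IL-23R cells and 7.64 ± 0.80 in IL-12Rβ2 cells. The activation-induced transcription factor gene EGR2 rose by 5.43 ± 0.43 and 5.09 ± 0.42, and the cytotoxic protease gene GZMB rose by 4.96 ± 0.31 and 5.42 ± 0.32 (n = 2 per group). Among cytokine genes, CSF2 rose by 4.34 ± 0.45 and 4.55 ± 0.45, and IFNG by 3.68 ± 0.59 and 4.03 ± 0.60. KLF2, a factor of resting cells, fell by 3.96 and 4.88. At 20 h the chemokine gene CCL1 had risen by 6.66 ± 0.55 and 6.69 ± 0.57, while MKI67, a marker of dividing cells, had fallen by 1.48 in IL-23R cells. All of these calls held with any one library left out. With the split term the values included 7.63 ± 0.51 and 7.66 ± 0.54 for TNFRSF9 and -1.48 ± 0.12 for MKI67.

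In IL-23R cells 3597 genes rose and 3322 fell at 4 h, and 1677 rose and 1587 fell at 20 h (4509 and 4364, then 2792 and 2614, with the split term). In IL-12Rβ2 cells 3455 rose and 3380 fell at 4 h, and 1554 rose and 1669 fell at 20 h (4268 and 4302, then 2652 and 2656, with the split term). Which direction had more genes depended on the processing. Without the filter on low counts it was 2773 and 3184, then 1048 and 1426, in IL-23R cells and 2520 and 3317, then 1174 and 1141, in IL-12Rβ2 cells. With only the groups compared, 901 rose and 829 fell at 20 h in IL-23R cells, and 959 and 998 in IL-12Rβ2 cells. For the 20 h comparisons, leaving out a library changed the number past the threshold from 3264 to 1902 without anti-CD3/CD28 library 2 and to 2127 without unstimulated library 2 of IL-23R cells. It changed from 3223 to 2126 without anti-CD3/CD28 library 1 and to 1848 without unstimulated library 1 of IL-12Rβ2 cells. Of the 24 T cell activation genes, 22 rose in IL-23R cells at 4 h (median log2 3.86, camera adjusted p = 1e-13, adjusted p = 0.0915 with an estimated correlation) and 17 at 20 h (median log2 2.29, camera adjusted p = 1.95e-12, adjusted p = 0.0915 with an estimated correlation). In IL-12Rβ2 cells 22 rose at 4 h (median log2 4.01, camera adjusted p = 7.36e-13, adjusted p = 0.0915 with an estimated correlation) and 17 at 20 h (median log2 2.53, camera adjusted p = 2.04e-11, adjusted p = 0.105 with an estimated correlation). Of the 18 cell division genes, 17 fell at 20 h in IL-23R cells (median log2 -1.26, camera adjusted p = 1.65e-16, adjusted p = 0.0915 with an estimated correlation) and 17 in IL-12Rβ2 cells (median log2 -1.10, camera adjusted p = 1.28e-15, adjusted p = 0.0953 with an estimated correlation). These controls were at 0 h. A comparison chosen after seeing the data set the antibodies with the cytokine against the cytokine alone at the same time, so that time was matched and the cytokine was on both sides. Of the genes past the threshold against 0 h in IL-23R cells, 4981 of 6919 passed in the same direction with time matched at 4 h and 15 in the opposite one, and 2220 of 3264 and 0 at 20 h. In IL-12Rβ2 cells 5352 of 6835 passed in the same direction and 6 in the opposite one at 4 h, and 2393 of 3223 and 0 at 20 h. TNFRSF9 rose by 6.21 ± 0.74 and 7.66 ± 0.80 at 4 h, CCL1 by 6.04 ± 0.57 and 6.54 ± 0.56 at 20 h, and KLF2 fell by 3.96 ± 0.44 and 4.46 ± 0.43 at 4 h. EGR2, GZMB, CSF2 and IFNG at 4 h in both lines, and MKI67 at 20 h in IL-23R cells (-1.35 ± 0.12), also passed in the same direction. Of the 18 cell division genes, 15 fell in each line at 20 h. Time in culture as the whole cause did not account for the genes that passed here, and the others stay open.

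**Figure D2:**
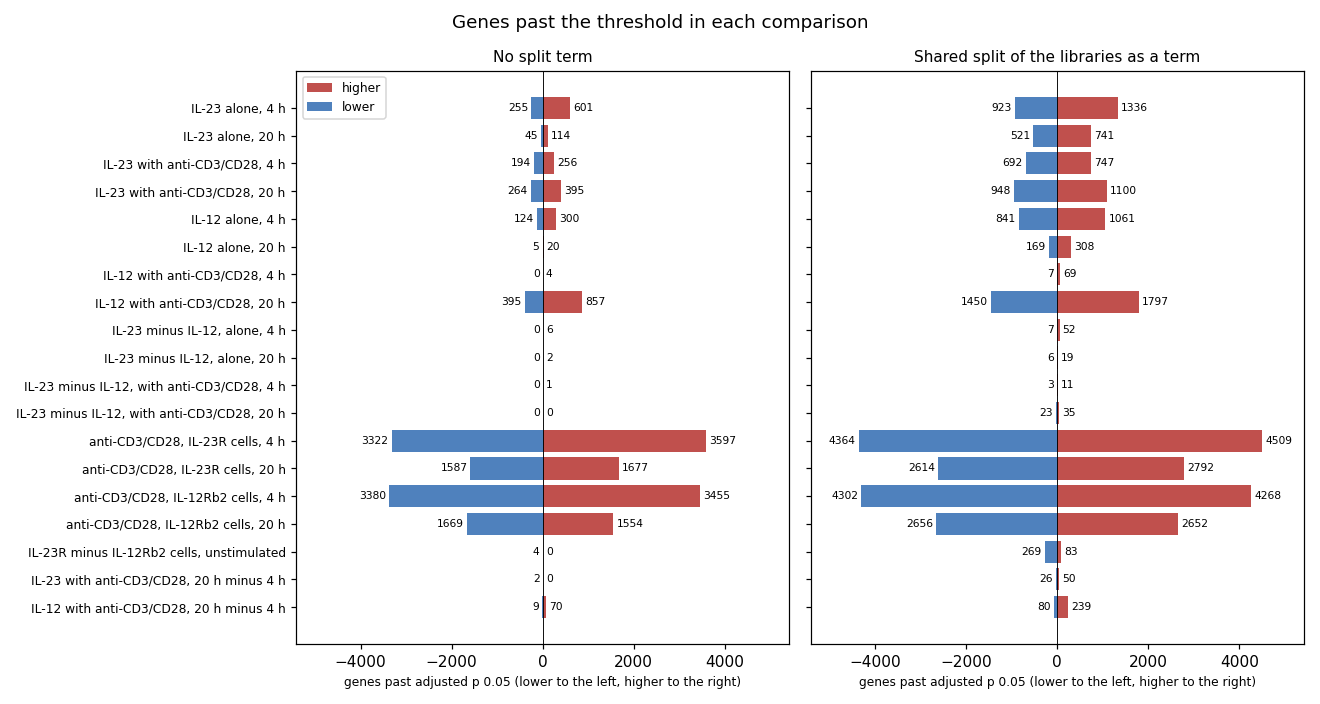
Genes past adjusted p 0.05 in each comparison, rising and falling, without and with the split term.

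With IL-23 alone for 4 h, against 0 h, some genes rose and others fell. The transcription factor genes BATF3 (3.07 ± 0.50), ETV7 (2.97 ± 0.37) and HLX (1.83 ± 0.21) rose. So did GZMB (2.67 ± 0.28) and the IL-2 receptor gene IL2RA (2.43 ± 0.25), and CD69, an early activation marker, fell by 1.63 ± 0.21 (n = 2 per group). BCL3, an NF-κB cofactor and STAT3 target (1.73 ± 0.28), and RSAD2, an interferon-stimulated gene (2.34 ± 0.39), also rose, while PER1, a clock gene induced by glucocorticoids, fell by 1.08 ± 0.17. These calls held with any one library left out. Values with the split term included 2.65 ± 0.25 for GZMB and -1.64 ± 0.20 for CD69. IL10, an anti-inflammatory cytokine gene, rose (3.16 ± 0.77, adjusted p = 0.0206; 3.25 ± 0.25 with the split term). It passed in 1 of 4 leave-one-out fits, with adjusted p up to 0.176 without either unstimulated library or IL-23 library 1. In all, 601 genes rose and 255 fell (1336 and 923 with the split term), against 181 and 195 without the filter on low counts. With only the groups compared, 0 genes passed at either time. There GZMB had the same direction (log2 2.66, adjusted p = 0.0538 at 4 h, and 2.02, 0.093 at 20 h), with fewer libraries to measure the spread. Leaving out any one of the 4 libraries gave 238 to 537. At 20 h, 114 rose and 45 fell (741 and 521 with the split term, and 26 and 10 without the filter). Leaving out any one of the 4 libraries gave 20 to 35. GZMB (2.02 ± 0.27; 2.02 ± 0.24 with the split term) and HLX (1.82 ± 0.21; 1.78 ± 0.18 with the split term) stayed past the threshold at 20 h in each of the leave-one-out fits. The other named genes past the threshold there did not.

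Of 24 T cell activation genes, 2 rose and 2 fell with IL-23 alone at 4 h (camera adjusted p = 0.345). IL2RA was among those that rose, and CD69 and the early response gene EGR1 fell. EGR1 (-2.21 ± 0.60, adjusted p = 0.039; -2.24 ± 0.52 with the split term) was lost without each of the 4 libraries (adjusted p up to 0.211) and without the filter (0.0543). Of 18 STAT3 target and cytokine feedback genes, 8 rose and 0 fell with IL-23 alone at 4 h, or 12 and 0 adjusted over the list alone (median log2 0.77, camera adjusted p = 1.69e-07, adjusted p = 0.0915 with an estimated correlation). At 20 h, 3 rose (median log2 0.71, camera adjusted p = 3.94e-07, adjusted p = 0.0915 with an estimated correlation). Of 22 interferon-stimulated genes, 6 rose at 4 h (median log2 0.32, camera adjusted p = 0.000325, adjusted p = 0.362 with an estimated correlation) and 1 at 20 h (median log2 0.42, camera adjusted p = 0.0266, adjusted p = 0.617 with an estimated correlation). The controls were at 0 h, so these comparisons do not by themselves separate IL-23 from time in culture.

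With anti-CD3/CD28 at matched times, IL-23 raised part of this set. At 4 h ETV7 (2.62 ± 0.36), PTGER3, a prostaglandin E2 receptor gene (2.55 ± 0.39), HLX (1.76 ± 0.20) and the interferon-induced GTPase gene GBP1 (1.02 ± 0.14) rose. GATA3, the Th2 transcription factor gene, fell by 0.98 ± 0.14 and BACH2, a repressor that restrains effector differentiation, by 0.85 ± 0.14 (n = 2 per group). These held with any one library left out. Values with the split term included 2.61 ± 0.34 for ETV7 and -0.98 ± 0.12 for GATA3. IL10 rose (3.25 ± 0.71, adjusted p = 0.017; 3.31 ± 0.21 with the split term). It passed in 2 of 4 leave-one-out fits, with adjusted p up to 0.2 without anti-CD3/CD28 library 2 or without IL-23 library 1. In all, 256 genes rose and 194 fell (747 and 692 with the split term), against 113 and 107 without the filter and 7 and 2 with only the groups compared. Of the genes named here, only ETV7 passed in the last of these (the others had adjusted p of 0.0723 to 0.146). The 450 became 131 without IL-23 library 1, 161 without anti-CD3/CD28 library 2 and 219 without anti-CD3/CD28 library 1. Of 22 interferon-stimulated genes 5 rose (median log2 0.59, camera adjusted p = 1.87e-06, adjusted p = 0.163 with an estimated correlation). Of 18 STAT3 target genes 5 rose (median log2 0.61, camera adjusted p = 7.25e-06, adjusted p = 0.114 with an estimated correlation).

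At 20 h, IL-23 with anti-CD3/CD28 raised HLX (2.21 ± 0.20), GZMB (2.14 ± 0.27), the interferon-induced chemokine gene CXCL10 (2.09 ± 0.30), IL2RA (1.48 ± 0.24) and SOCS3 (1.34 ± 0.18). It lowered BACH2 by 1.27 ± 0.14 and the growth factor receptor gene KIT by 3.71 ± 0.54 (n = 2 per group). These held with any one library left out. Values with the split term included 2.15 ± 0.24 for GZMB and -3.71 ± 0.35 for KIT. IL10 rose (4.67 ± 0.81, adjusted p = 0.00359; 4.66 ± 0.26 with the split term) and was lost only without anti-CD3/CD28 library 1 (adjusted p = 0.0696). TBX21, the Th1 transcription factor gene, rose (1.60 ± 0.33, adjusted p = 0.01; 1.61 ± 0.25 with the split term) and passed in 1 of 4 leave-one-out fits (adjusted p up to 0.154), the one without anti-CD3/CD28 library 2. The readthrough transcript PALM2-AKAP2 had 306 and 68 counts with IL-23 and 1 and 1 without it, and its reads are shared with AKAP2, so the gene of origin is uncertain. It passed in 2 of 4 leave-one-out fits and was lost without either anti-CD3/CD28 library (adjusted p up to 0.0873). In all, 395 genes rose and 264 fell (1100 and 948 with the split term), against 165 and 187 without the filter and 47 and 47 with only the groups compared. In the last of these HLX, IL2RA, KIT, IL10 and TBX21 were lost (adjusted p of 0.0541 to 0.0719). Leaving out any one of the 4 libraries gave 109 to 402. Of 18 glycolysis genes 8 rose (median log2 0.64, camera adjusted p = 3.98e-13, adjusted p = 0.152 with an estimated correlation), among them PGK1 (0.95 ± 0.17) and ENO1 (0.97 ± 0.20). PGK1 was lost without IL-23 library 1 or anti-CD3/CD28 library 1, and ENO1 without these or anti-CD3/CD28 library 2 (adjusted p up to 0.072 and 0.11). Both were lost with only the groups compared (0.0682 and 0.0598), and ENO1 without the filter (0.0628). Of 18 cell division genes, 11 rose (median log2 0.58, camera adjusted p = 6.51e-14, adjusted p = 0.114 with an estimated correlation). Among 18 STAT3 target genes 8 rose and 1 fell (median log2 0.84, camera adjusted p = 4.77e-06, adjusted p = 0.114 with an estimated correlation). The cell division genes rose from their level with anti-CD3/CD28 alone. Against IL-23 alone at 20 h, IL-23 with anti-CD3/CD28 lowered 15 of the 18 (median log2 -0.95).

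With IL-12 alone for 4 h, against 0 h, PTGER3 (2.67 ± 0.37), the adhesion molecule gene CEACAM1 (1.83 ± 0.25) and GBP1 (1.06 ± 0.14) rose. SOCS3 fell by 1.61 ± 0.18 and CD69 by 1.66 ± 0.21 (n = 2 per group). These held with any one library left out. Values with the split term included 2.71 ± 0.26 for PTGER3 and -1.61 ± 0.17 for SOCS3. SOCS3 also fell from 0 h without IL-12, with anti-CD3/CD28 (-0.92 ± 0.18 at 4 h and -1.39 ± 0.18 at 20 h), and against that control at the same time it did not pass with IL-12 (0.69 ± 0.18, adjusted p = 0.307 at 4 h, and 0.28 ± 0.18, adjusted p = 0.376 at 20 h). Its fall is therefore not assigned to IL-12. IFNG, the cytokine gene that marks Th1 cells, did not pass (1.97 ± 0.55, adjusted p = 0.062; 1.98 ± 0.53, adjusted p = 0.0203 with the split term). In all, 300 genes rose and 124 fell (1061 and 841 with the split term), against 110 and 18 without the filter. With only the groups compared, 0 genes passed at either time, and PTGER3 had the same direction (log2 2.69, adjusted p = 0.223 at 4 h). The 424 became 21 without IL-12 library 1, 32 without unstimulated library 1 and 79 without unstimulated library 2. At 20 h, 20 rose and 5 fell (308 and 169 with the split term, and 15 and 2 without the filter). The 25 became 8 without IL-12 library 1, 96 without IL-12 library 2, 4 without unstimulated library 1 and 7 without unstimulated library 2. The ATP receptor gene P2RX5 rose (1.86 ± 0.21; 1.86 ± 0.18 with the split term) and SOCS3 fell (-1.48 ± 0.18; -1.48 ± 0.17 with the split term) with any one library left out. The other named genes past the threshold at 20 h did not hold in this way. P2RX5 shares reads with a readthrough transcript, so its share is uncertain. Here too the controls were at 0 h, and these comparisons do not by themselves separate IL-12 from time in culture.

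With IL-12 and anti-CD3/CD28, few genes passed the threshold at 4 h and more at 20 h. At 4 h, 4 genes rose and 0 fell with edgeR (69 and 7 with the split term), against 63 past the threshold with DESeq2, 27 without the filter and 0 with only the groups compared. In edgeR 791 had unadjusted p below 0.05, against 778 if p-values were evenly spread. The same fit gave 336 for the IL-23 minus IL-12 response alone at 20 h and 384 with anti-CD3/CD28 at 4 h. Counts without an effect can thus lie under 778, so 791 does not show that few genes responded. The 4 were SERINC5, a membrane protein gene (1.16 ± 0.15), the cytoskeletal gene FRMD4B (1.43 ± 0.24), KIAA1671 (1.38 ± 0.21) and the kinase gene MAP3K8 (0.84 ± 0.13; n = 2 per group). With the split term the values were 1.15 ± 0.14, 1.45 ± 0.18, 1.37 ± 0.11 and 0.84 ± 0.12. FRMD4B passed in 0 of 4 leave-one-out fits and the others each in 1 of 4, the fit without IL-12 library 1 (adjusted p up to 0.602, 0.211 for SERINC5, and 0.339 for KIAA1671 and MAP3K8). The count became 1 without anti-CD3/CD28 library 1, 0 without anti-CD3/CD28 library 2, 13 without IL-12 library 1 and 0 without IL-12 library 2. STAT3 target genes (median log2 0.51, camera adjusted p = 3.99e-06, adjusted p = 0.114 with an estimated correlation), Th1 genes (median log2 0.31, camera adjusted p = 0.0241, adjusted p = 0.694 with an estimated correlation) and inflammatory Th17 genes (median log2 0.40, camera adjusted p = 0.0312, adjusted p = 0.645 with an estimated correlation) were higher as lists, with 0 members past the threshold.

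At 20 h, IL-12 with anti-CD3/CD28 raised all 18 cell division genes (median log2 0.84, camera adjusted p = 2.51e-20, adjusted p = 0.0915 with an estimated correlation), such as CDK1 (1.22 ± 0.13) and MKI67 (0.73 ± 0.12). It also raised NT5C1A, a nucleotidase gene (3.93 ± 0.57), P2RX5 (2.97 ± 0.22) and CXCL10 (1.69 ± 0.29; n = 2 per group). It lowered EGR3, an activation-induced transcription factor gene, by 1.75 ± 0.34, GATA3 by 0.85 ± 0.14 and the T cell receptor kinase gene ZAP70 by 0.98 ± 0.15. The calls for these genes held with any one library left out. Values with the split term included 1.22 ± 0.11 for CDK1 and -1.74 ± 0.23 for EGR3. IFNG rose (2.34 ± 0.55, adjusted p = 0.014; 2.36 ± 0.52 with the split term). It passed in 1 of 4 leave-one-out fits, with adjusted p up to 0.133 without either anti-CD3/CD28 library or IL-12 library 2. IL10 rose (3.07 ± 0.74, adjusted p = 0.0166; 3.08 ± 0.23 with the split term). It passed in 1 of 4 leave-one-out fits, with adjusted p up to 0.175 without either anti-CD3/CD28 library or IL-12 library 1, and was lost with only the groups compared (0.0619). The IL10 responses to IL-23 and IL-12 did not pass a test of their difference at 20 h without the split term (1.60 ± 1.1, adjusted p = 0.933). This does not show that they were alike, as the responses with the term were 4.66 ± 0.26 and 3.08 ± 0.23. TBX21 rose (1.36 ± 0.33, adjusted p = 0.0164; 1.37 ± 0.25 with the split term) and passed in 0 of 4 (adjusted p up to 0.141). The cell division genes rose from their level with anti-CD3/CD28 alone. Against IL-12 alone at 20 h, IL-12 with anti-CD3/CD28 lowered 15 of the 18 (median log2 -0.64). With IL-12 and anti-CD3/CD28 against anti-CD3/CD28, 857 genes rose and 395 fell in all (1797 and 1450 with the split term). Without the filter it was 517 and 110, and with only the groups compared 153 and 48. The 1252 became 294 without IL-12 library 2, 448 without anti-CD3/CD28 library 2 and 670 without anti-CD3/CD28 library 1.

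**Figure D3:**
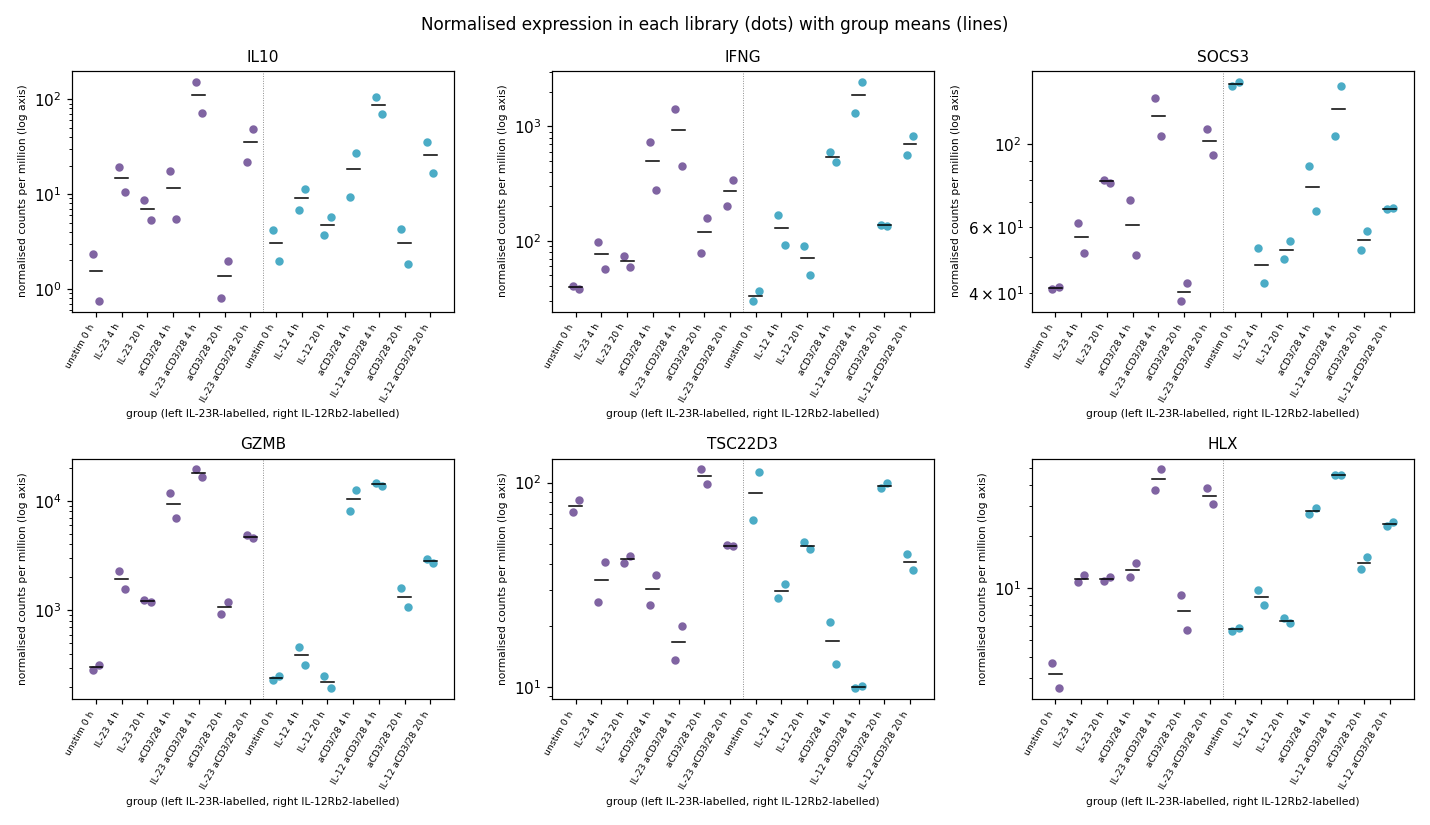
CPM of IL10, IFNG, SOCS3, GZMB, TSC22D3 and HLX in each library, by group. Each point is 1 library.

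The series title concerns IL-23, an inflammatory Th17 state and glucocorticoid receptor activity. IL17A, the Th17 cytokine gene, rose with anti-CD3/CD28 at 4 h in IL-23R cells (4.26 ± 0.84; 4.46 ± 0.70 with the split term; n = 2 per group), in all leave-one-out fits. With IL-23 added it did not pass at 4 h (-1.18 ± 0.71, adjusted p = 0.514) or 20 h (-0.76 ± 0.84, adjusted p = 0.744). Of 20 Th17 genes, 1 rose and 0 fell with IL-23 and anti-CD3/CD28 at 4 h (camera adjusted p = 0.288). At 20 h, 0 rose and 1 fell (camera adjusted p = 0.998). Of 20 inflammatory Th17 genes, 1 rose and 0 fell at 4 h (camera adjusted p = 0.449). At 20 h, 3 rose and 1 fell (camera adjusted p = 0.28).

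Genes induced by the glucocorticoid receptor were lower with each cytokine in some comparisons. TSC22D3, which encodes the glucocorticoid-induced leucine zipper, fell with IL-23 alone at 4 h (-1.20 ± 0.26) and with IL-23 and anti-CD3/CD28 at 20 h (-1.13 ± 0.26). It also fell with IL-12 alone at 4 h (-1.60 ± 0.26) and with IL-12 and anti-CD3/CD28 at 20 h (-1.24 ± 0.26; n = 2 per group). With the split term the values were -1.22 ± 0.20, -1.12 ± 0.20, -1.56 ± 0.20 and -1.23 ± 0.20. These passed in 2 of 4, 0 of 4, 2 of 4 and 3 of 4 leave-one-out fits, with adjusted p up to 0.177, 0.141, 0.122 and 0.117. The first was lost without unstimulated library 2 or IL-23 library 1, the second without each of the 4 libraries, the third without unstimulated library 2 or IL-12 library 1, and the last without IL-12 library 2. NR3C1, which encodes the receptor itself, fell with IL-23 and anti-CD3/CD28 at 20 h (-0.60 ± 0.12, adjusted p = 0.00881; -0.60 ± 0.11 with the split term), and passed in 1 of 4 leave-one-out fits (adjusted p up to 0.116), the one without anti-CD3/CD28 library 2. With only the groups compared NR3C1 was lost (0.0877), and so was TSC22D3 with IL-23 alone (0.111) and with IL-12 alone (0.225). FKBP5, another target of the receptor, did not pass in that comparison (0.37 ± 0.47, adjusted p = 0.781; 0.33 ± 0.12, adjusted p = 0.0778 with the split term). Of 24 genes in the list, 3 fell and 0 rose with IL-23 alone at 4 h (median log2 -0.46, camera adjusted p = 4.09e-05, adjusted p = 0.129 with an estimated correlation). In the list 4 fell with IL-23 and anti-CD3/CD28 at 20 h (median log2 -0.21, camera adjusted p = 0.0147, adjusted p = 0.478 with an estimated correlation). With IL-12 alone, 5 fell at 4 h (median log2 -0.60, camera adjusted p = 3.82e-07, adjusted p = 0.0915 with an estimated correlation) and 0 at 20 h (median log2 -0.28, camera adjusted p = 0.000411, adjusted p = 0.191 with an estimated correlation). The cells with a cytokine alone were compared with 0 h. The list did not pass with IL-12 and anti-CD3/CD28 at 20 h (camera adjusted p = 0.105). The difference between the IL-23 and IL-12 responses did not pass there either (camera adjusted p = 0.699).

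**Figure D4:**
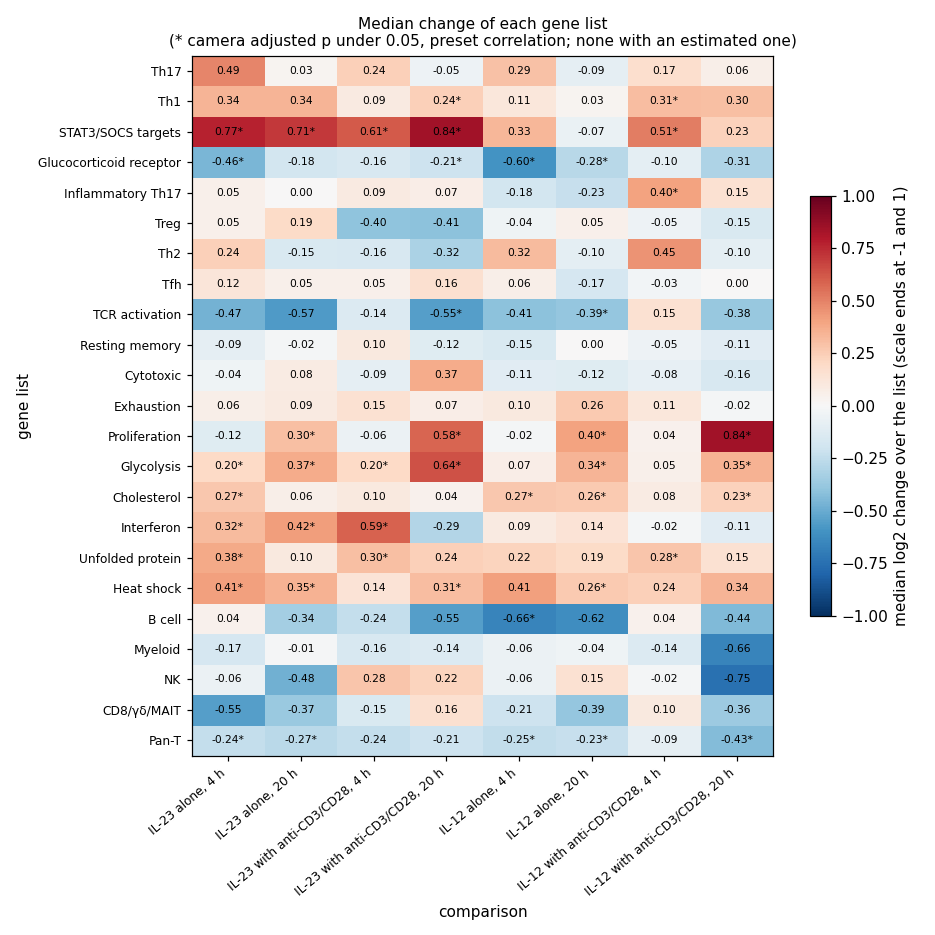
Median log2 change of each gene list in the 8 comparisons of a cytokine with its control.

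Few genes passed a test of the difference between the responses to the cytokines. IL-23 was given only to IL-23R cells and IL-12 only to IL-12Rβ2 cells. A difference between the responses therefore does not separate the cytokines from the receptor lines. Each difference rested on 8 libraries, and how often such a test finds a true difference was not simulated. Unadjusted p was below 0.05 for 779 genes at 4 h and 336 at 20 h without anti-CD3/CD28, and for 384 at 4 h with it. Evenly spread p-values would give 778. Few calls therefore do not show that the responses were alike. Without anti-CD3/CD28, the IL-23 response minus the IL-12 response was positive for SOCS3 (2.06 ± 0.26, adjusted p = 0.00213 at 4 h, and 2.43 ± 0.26, adjusted p = 0.00041 at 20 h; n = 2 per group). It was also positive for CMTM7, a membrane protein gene (1.25 ± 0.15, adjusted p = 0.00183 at 4 h) and CNP, a phosphodiesterase gene (0.86 ± 0.11, adjusted p = 0.00272 at 4 h). All held with any one library left out (2.07 ± 0.25, 2.43 ± 0.24, 1.25 ± 0.13 and 0.86 ± 0.11 with the split term). For SOCS3 the change was 0.45 ± 0.18, adjusted p = 0.17 with IL-23 and -1.61 ± 0.18, adjusted p = 0.000355 with IL-12 at 4 h, from unstimulated means of 41.2 and 145 CPM. With the cytokine the means were 56.3 and 47.5 CPM at 4 h, and 79.5 and 52.1 CPM at 20 h. The lines were thus further apart before stimulation than after, and most of the SOCS3 difference is the gap between the unstimulated cells. WDR59 also passed (0.88 ± 0.15, adjusted p = 0.0496; 0.89 ± 0.13 with the split term), but in 0 of 8 leave-one-out fits (adjusted p up to 0.404). At 4 h 6 genes passed, all positive (52 positive and 7 negative with the split term), against 3 without the filter, where CNP was lost (adjusted p = 0.49), 35 with DESeq2 and 0 with only the groups compared. There, 3 passed without IL-12 library 2 or without unstimulated library 1 of IL-23R cells. At 20 h 2 passed (19 positive and 6 negative with the split term), against 1 without the filter, 1 with only the groups compared and 13 with DESeq2. SOCS3 passed in all of these at 20 h. Leaving out any one of the 8 libraries gave 1. STAT3 target genes were higher as a list at 4 h (median log2 0.42, camera adjusted p = 1.71e-05, adjusted p = 0.129 with an estimated correlation) and 20 h (median log2 0.33, camera adjusted p = 8.8e-12, adjusted p = 0.0915 with an estimated correlation). The same unstimulated libraries enter these differences, and in them the list was lower in IL-23R cells (median log2 -0.48), so the differences may come from the start as well as from the cytokines.

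With anti-CD3/CD28, the difference at 4 h passed for 1 gene (n = 2 per group), against 0 without the filter or with only the groups compared, 7 with DESeq2, and 11 positive and 3 negative with the split term, and 0 genes passed in 6 of the 8 leave-one-out fits. At 20 h, 0 genes passed with edgeR, and 923 had unadjusted p below 0.05 (778 if p-values were evenly spread). There 32 passed with DESeq2, and 35 were positive and 23 negative with the split term. Without IL-23 library 2, 33 passed. At 20 h, cell division genes rose less with IL-23 in IL-23R cells than with IL-12 in IL-12Rβ2 cells (median log2 -0.32, camera adjusted p = 2.79e-06, adjusted p = 0.413 with an estimated correlation). The difference was positive for glycolysis genes (median log2 0.30, camera adjusted p = 0.000961, adjusted p = 0.617 with an estimated correlation) and STAT3 target genes (median log2 0.40, camera adjusted p = 0.0147, adjusted p = 0.515 with an estimated correlation). Of the genes past the threshold with anti-CD3/CD28 at 20 h, 228 rose with both cytokines, against 21.7 expected if the calls were independent. With both, 117 fell, against 6.7, and 0 went opposite ways. Both comparisons used the same estimate of the spread of each gene, so the calls were not independent and these expected numbers are only a guide. Over the 15568 genes other than the receptor genes, the log2 changes of the cytokines correlated with r = 0.46 there, 0.36 with anti-CD3/CD28 at 4 h, 0.41 alone at 4 h and 0.38 alone at 20 h.

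The effects of the cytokines with anti-CD3/CD28 at 20 h and 4 h were compared within each line, and the counts depended on the fit. For IL-12, the 20 h minus 4 h difference in log2 change was positive for 70 genes and negative for 9 (239 and 80 with the split term), against 0 in all without the filter or with only the groups compared and 197 in all with DESeq2. Among the 79 were P2RX5 (1.80 ± 0.30), the cell cycle kinase gene CDK1 (1.12 ± 0.18) and GPR35, a receptor gene (-1.45 ± 0.24; n = 2 per group). With the split term the values were 1.80 ± 0.27, 1.12 ± 0.16 and -1.46 ± 0.24. Each of these 3 passed in 4 of 8 leave-one-out fits, and all were lost without anti-CD3/CD28 4 h library 2, IL-12 4 h library 1 or IL-12 20 h library 2. P2RX5 was also lost without anti-CD3/CD28 20 h library 1, and CDK1 and GPR35 without anti-CD3/CD28 20 h library 2 (adjusted p up to 0.0813 for each). The 79 became 0 without IL-12 20 h library 2 or IL-12 4 h library 1, and 2 without anti-CD3/CD28 library 2 of either time. The count became 25 without anti-CD3/CD28 20 h library 1, 45 without anti-CD3/CD28 4 h library 1 and 47 without IL-12 4 h library 2. Cell division genes were higher as a list (median log2 0.78, camera adjusted p = 7.02e-24, adjusted p = 0.0915 with an estimated correlation). For IL-23, the difference was positive for 0 genes and negative for 2 (50 and 26 with the split term), against 1 in all without the filter, 0 with only the groups compared and 74 with DESeq2. Among them was the clock gene NR1D2 (-1.71 ± 0.26, adjusted p = 0.0347; -1.70 ± 0.23 with the split term), which passed in 2 of 8 leave-one-out fits, those without IL-23 library 2 of either time (adjusted p up to 0.309). It was lost without the filter (0.0532) and with only the groups compared (0.568). Interferon-stimulated genes were lower as a list (median log2 -0.73, camera adjusted p = 3.51e-09, adjusted p = 0.0949 with an estimated correlation) and cell division genes higher (median log2 0.59, camera adjusted p = 8.4e-17, adjusted p = 0.0915 with an estimated correlation). The 2 became 1 in 5 of the 8 fits, 3 without anti-CD3/CD28 20 h library 2, 4 without IL-23 4 h library 2 and 37 without IL-23 20 h library 2. The difference between the cytokines in this respect was not tested.

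The other lists are given for IL-23 with anti-CD3/CD28 at 20 h, as genes past the threshold. Of 20 Th1 genes 3 rose and 1 fell (median log2 0.24, camera adjusted p = 0.0345, adjusted p = 0.722 with an estimated correlation). Of 24 T cell activation genes 1 rose and 3 fell (median log2 -0.55, camera adjusted p = 0.0336, adjusted p = 0.694 with an estimated correlation). NR4A3, an activation-induced nuclear receptor gene, was among those that fell (-1.82 ± 0.30; -1.85 ± 0.28 with the split term; lost without IL-23 library 1, adjusted p = 0.072, and with only the groups compared, 0.0763). Among regulatory genes 2 rose and 1 fell of 14 (camera adjusted p = 0.841). Of 14 Th2 genes 0 rose and 0 fell (0.126), and of 13 follicular helper genes 0 rose and 1 fell (0.801). Of 16 resting memory genes 0 rose and 2 fell (0.184). Of 13 cytotoxic genes 2 rose and 0 fell (0.0982), and of 10 inhibitory receptor genes 0 rose and 1 fell (0.61). The counts that rose and fell among cholesterol synthesis genes were 1 and 0 of 21 (0.4), among interferon-stimulated genes 1 and 0 of 22 (0.352), and among unfolded protein response genes 0 and 0 of 12 (0.0512).

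Heat shock genes, a mark of handling stress, had 0 of 11 past the threshold in the same comparison (median log2 0.31, camera adjusted p = 0.00974, adjusted p = 0.617 with an estimated correlation). Among markers of other cells, 1 of 4 B cell genes rose (camera adjusted p = 0.527), 0 of 6 myeloid genes (0.633), 0 of 3 NK cell genes (0.851) and 1 of 6 CD8, γδ and MAIT genes (0.843). In the same order, 0, 0, 0 and 0 fell. Of 11 T cell genes, 1 rose and 1 fell (camera adjusted p = 0.377). Mitochondrially encoded mRNAs were not measured in this table.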

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

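The tests of the depth of the libraries, of the 3 genes on or off between the sides, of swapped labels, of too few counts and of reads not counted, the markers and IL12RB2 between the sides, and the single pairs of libraries were chosen after the results were seen, and the others were written down before.

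The IL-23 response minus the IL-12 response, without anti-CD3/CD28, was a planned comparison and was flagged because genes and lists differed between the groups. In this section, lists said to differ passed camera with the preset correlation, and 0 of them held with an estimated one. At 4 h 6 genes passed: SOCS3 (log2 2.06), CMTM7 (1.25), WDR59 (0.88) and CNP (0.86), and outside the naming rule and chosen after seeing the data the receptor tyrosine kinase gene RET (4.14) and FAM110C (1.76). FAM110C (adjusted p = 0.0496) was lost with any one library left out (up to 0.404), and RET without unstimulated library 1 of IL-23R cells (0.088) or IL-12 library 2 (0.0778). STAT3 target genes (median 0.42; adjusted p = 0.129) and interferon-stimulated genes (median 0.24; 0.645) differed as lists, where the adjusted p are with an estimated correlation. At 20 h 2 genes passed, SOCS3 (2.43) and RET (3.64), of which RET was lost with any one library left out (adjusted p up to 0.379). There STAT3 target genes (0.33; adjusted p = 0.0915 with an estimated correlation), inflammatory Th17 genes (0.20; 0.617), regulatory genes (0.20; 0.271) and cholesterol synthesis genes (-0.23; 0.552) differed.

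The same difference with anti-CD3/CD28 passed for 1 gene at 4 h. There T cell activation genes (median -0.35; adjusted p = 0.645 with an estimated correlation), glycolysis genes (0.19; 0.743) and interferon-stimulated genes (0.43; 0.129) differed as lists. At 20 h the lists that differed were STAT3 target genes (0.40; adjusted p = 0.515 with an estimated correlation), cell division genes (-0.32; 0.413), glycolysis genes (0.30; 0.617) and T cell genes (0.12; 0.617).

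The 20 h response minus the 4 h response, with anti-CD3/CD28, was tested for each cytokine in the same way. For IL-23 2 genes passed, among them NR1D2 (-1.71), and cytotoxic genes (median 0.49; adjusted p = 0.609 with an estimated correlation), cell division genes (0.59; 0.0915), glycolysis genes (0.53; 0.362) and interferon-stimulated genes (-0.73; 0.0949) differed. For IL-12 79 genes passed, with P2RX5 (1.80), RAD51AP1 (1.17), DEPDC1 (1.17) and ERCC6L (1.15) positive and SRGAP3 (-2.77), NLRP6 (-1.51), GPR35 (-1.45) and SERINC5 (-1.10) negative. A negative value can be a fall at 20 h, as for SRGAP3 (log2 -2.61 at 20 h) and NLRP6 (-2.03). RAD51AP1 and ERCC6L passed in 3 of 8 leave-one-out fits, DEPDC1, SRGAP3 and NLRP6 in 1 of 8 and SERINC5 in 0 of 8. There Th2 genes (median -0.55; adjusted p = 0.424 with an estimated correlation), T cell activation genes (-0.41; 0.617), cell division genes (0.78; 0.0915), glycolysis genes (0.36; 0.58) and T cell genes (-0.17; 0.617) differed. Up to 0.34% of the counts of a library stood on lines without a gene name and were not analysed here.

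The shared difference between the libraries of every group was not what sequencing depth would give, because the library of side 1 was the deeper one in 7 of 14 groups. For one other cell type mixed into one side, the prediction was that nearly all separated genes would be higher on that side. Of the 159 separated genes, 29.6% were higher on the side with fewer of them. Such a mixture would also dilute the genes of the other cells on that side, so this count cannot decide. Between the sides, the median of the 3 NK cell genes was higher on side 1 in all 14 groups (log2 0.89) and that of the CD8, γδ and MAIT genes lower in all 14 (-0.29). IL12RB2 held 1.25% to 1.78% of the counts on side 1 of IL-12Rβ2 cells and 2.26% to 2.88% on side 2. A different mixture of cells or level of the vector on each side therefore stays open and was not tested. Donors or cultures that differ between the sides cannot be told apart from another stable difference between sources, with 3 genes at 10 counts or fewer on one side and 100 or more on the other.

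IL23R was not higher in IL-23R cells. Labels swapped between the receptors were not a fit, because IL12RB2 held at most 0.013% of the counts in an IL-23R library, and neither were too few counts, because the lowest count of IL23R in these cells was 15. Reads of an introduced receptor that were not counted to IL23R, as with a changed coding sequence, could give this and cannot be told apart from cells that respond through their own receptor, as 450 genes passed with IL-23 and anti-CD3/CD28 at 4 h.

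Of the genes past the threshold with each cytokine alone at 4 h, 244 moved the same way with both. Time in culture as the whole cause did not account for them, because with anti-CD3/CD28 at 4 h, against a control of the same time, 96.3% of them with IL-23 and 93.9% with IL-12 had the sign they had alone, against 65.1% and 64.5% of the other genes. The median log2 change in that direction was 0.35 and 0.26, and over single pairs of libraries 0.21 to 0.55 and 0.16 to 0.37. Few passed the threshold there, 57 with IL-23 and 1 with IL-12, so this holds for the genes as a set. Part of their change could still come from time in culture, which these groups leave open.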

How the results depend on the processing

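No call for a named gene or a list turned its direction in an alternative, while the numbers of genes past the threshold depended on the fit, and the cause was not tested. The balance of genes that rose and fell did turn: with DESeq2 size factors antibodies IL-12Rβ2 cells 20 h 1554 and 1669 to 1674 and 1578; with the Wald test antibodies IL-23R cells 20 h 1677 and 1587 to 1750 and 1758, antibodies IL-12Rβ2 cells 20 h 1554 and 1669 to 1807 and 1665, IL-23 with antibodies 20 h minus 4 h 0 and 2 to 48 and 26; with no filter IL-23 alone 4 h 601 and 255 to 181 and 195, IL-23 with antibodies 20 h 395 and 264 to 165 and 187, antibodies IL-23R cells 4 h 3597 and 3322 to 2773 and 3184, antibodies IL-23R cells 20 h 1677 and 1587 to 1048 and 1426, antibodies IL-12Rβ2 cells 4 h 3455 and 3380 to 2520 and 3317, antibodies IL-12Rβ2 cells 20 h 1554 and 1669 to 1174 and 1141; with the split term antibodies IL-12Rβ2 cells 4 h 3455 and 3380 to 4268 and 4302, IL-23 with antibodies 20 h minus 4 h 0 and 2 to 50 and 26. The split term, 1 subtracted and the replicate block were chosen after the data were seen. Of the results for named genes, 1629 stayed and 7 weakened with DESeq2 size factors, 1630 and 7 with 1 subtracted, 1461 and 175 without the filter, 1304 and 329 with only the groups compared, 1573 and 6 with the Wald test, 1610 and 24 with the replicate block, and 1478 and 0 with the split term. Others became calls: 58 with the Wald test, 159 with the split term, 4 with only the groups compared, 3 with the block, and 1 each with DESeq2 size factors and without the filter. The results that stayed include list genes that passed the threshold in neither fit. Among calls alone, the share that weakened would therefore be larger. The adapter index set as a covariate was not run, because the table's columns could not be tied to single samples. The sample labels share no replicate numbers, but the columns of the table carry 1 or 2 within each group. Libraries of the same number did not deviate together (correlations of -0.66 to 0.68 over 91 pairs of groups), so the numbers were not taken to pair the libraries. With these numbers as a replicate block, the counts moved by over 1.5 times for IL-12 alone 20 h 12, IL-23 minus IL-12 alone 20 h 1, IL-23 with antibodies 20 h minus 4 h 1. The split term is a block found in the data, not in the labels. Antibodies below means anti-CD3/CD28.

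Genes past the threshold, each setting against the count with all libraries and no covariate (IL-23 alone 4 h 856, IL-23 alone 20 h 159, IL-23 with antibodies 4 h 450, IL-23 with antibodies 20 h 659, IL-12 alone 4 h 424, IL-12 alone 20 h 25, IL-12 with antibodies 4 h 4, IL-12 with antibodies 20 h 1252, IL-23 minus IL-12 alone 4 h 6, IL-23 minus IL-12 alone 20 h 2, IL-23 minus IL-12 with antibodies 4 h 1, IL-23 minus IL-12 with antibodies 20 h 0, antibodies IL-23R cells 4 h 6919, antibodies IL-23R cells 20 h 3264, antibodies IL-12Rβ2 cells 4 h 6835, antibodies IL-12Rβ2 cells 20 h 3223, IL-23R minus IL-12Rβ2 cells unstimulated 4, IL-23 with antibodies 20 h minus 4 h 2, IL-12 with antibodies 20 h minus 4 h 79), were as follows where they moved by over 1.5 times. With the Wald test of DESeq2: IL-23 alone 20 h 556, IL-23 with antibodies 4 h 738, IL-23 with antibodies 20 h 1069, IL-12 alone 4 h 1045, IL-12 alone 20 h 301, IL-12 with antibodies 4 h 63, IL-23 minus IL-12 alone 4 h 35, IL-23 minus IL-12 alone 20 h 13, IL-23 minus IL-12 with antibodies 4 h 7, IL-23 minus IL-12 with antibodies 20 h 32, IL-23R minus IL-12Rβ2 cells unstimulated 95, IL-23 with antibodies 20 h minus 4 h 74, IL-12 with antibodies 20 h minus 4 h 197. With no filter on low counts: IL-23 alone 4 h 376, IL-23 alone 20 h 36, IL-23 with antibodies 4 h 220, IL-23 with antibodies 20 h 352, IL-12 alone 4 h 128, IL-12 with antibodies 4 h 27, IL-12 with antibodies 20 h 627, IL-23 minus IL-12 alone 4 h 3, IL-23 minus IL-12 alone 20 h 1, IL-23 minus IL-12 with antibodies 4 h 0, IL-23 with antibodies 20 h minus 4 h 1, IL-12 with antibodies 20 h minus 4 h 0. With only the groups compared: IL-23 alone 4 h 0, IL-23 alone 20 h 0, IL-23 with antibodies 4 h 9, IL-23 with antibodies 20 h 94, IL-12 alone 4 h 0, IL-12 alone 20 h 0, IL-12 with antibodies 4 h 0, IL-12 with antibodies 20 h 201, IL-23 minus IL-12 alone 4 h 0, IL-23 minus IL-12 alone 20 h 1, IL-23 minus IL-12 with antibodies 4 h 0, antibodies IL-23R cells 20 h 1730, antibodies IL-12Rβ2 cells 20 h 1957, IL-23R minus IL-12Rβ2 cells unstimulated 2, IL-23 with antibodies 20 h minus 4 h 0, IL-12 with antibodies 20 h minus 4 h 0. With the split term: IL-23 alone 4 h 2259, IL-23 alone 20 h 1262, IL-23 with antibodies 4 h 1439, IL-23 with antibodies 20 h 2048, IL-12 alone 4 h 1902, IL-12 alone 20 h 477, IL-12 with antibodies 4 h 76, IL-12 with antibodies 20 h 3247, IL-23 minus IL-12 alone 4 h 59, IL-23 minus IL-12 alone 20 h 25, IL-23 minus IL-12 with antibodies 4 h 14, IL-23 minus IL-12 with antibodies 20 h 58, antibodies IL-23R cells 20 h 5406, antibodies IL-12Rβ2 cells 20 h 5308, IL-23R minus IL-12Rβ2 cells unstimulated 352, IL-23 with antibodies 20 h minus 4 h 76, IL-12 with antibodies 20 h minus 4 h 319. With 1 subtracted from every value: IL-12 alone 20 h 16, IL-23 minus IL-12 alone 20 h 1. With each library left out in turn, for every comparison whether or not it moved that far, lowest to highest: IL-23 alone 4 h 238 to 537, IL-23 alone 20 h 20 to 35, IL-23 with antibodies 4 h 131 to 386, IL-23 with antibodies 20 h 109 to 402, IL-12 alone 4 h 21 to 382, IL-12 alone 20 h 4 to 96, IL-12 with antibodies 4 h 0 to 13, IL-12 with antibodies 20 h 294 to 901, IL-23 minus IL-12 alone 4 h 3 to 6, IL-23 minus IL-12 alone 20 h 1 to 1, IL-23 minus IL-12 with antibodies 4 h 0 to 1, IL-23 minus IL-12 with antibodies 20 h 0 to 33, antibodies IL-23R cells 4 h 5023 to 6060, antibodies IL-23R cells 20 h 1902 to 2557, antibodies IL-12Rβ2 cells 4 h 5294 to 5738, antibodies IL-12Rβ2 cells 20 h 1848 to 2309, IL-23R minus IL-12Rβ2 cells unstimulated 2 to 5, IL-23 with antibodies 20 h minus 4 h 1 to 37, IL-12 with antibodies 20 h minus 4 h 0 to 76.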

Other observations

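Of the lists that stood for other processes, the cholesterol synthesis genes past the threshold were mostly lower at 4 h and higher at 20 h with anti-CD3/CD28, each against 0 h. In IL-23R cells 11 of 21 fell and 4 rose at 4 h (camera adjusted p = 0.235), and 11 rose and 0 fell at 20 h (median log2 0.54, camera adjusted p = 6.73e-05, adjusted p = 0.531 with an estimated correlation). In IL-12Rβ2 cells 12 fell and 6 rose at 4 h (camera adjusted p = 0.336), and 11 rose and 1 fell at 20 h (median log2 0.50, camera adjusted p = 4.85e-05, adjusted p = 0.529 with an estimated correlation). The difference between the times was not tested.

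Follicular helper genes rose with anti-CD3/CD28 at 20 h, against 0 h, 8 of 13 in IL-23R cells (median log2 1.18, camera adjusted p = 8.7e-06, adjusted p = 0.0915 with an estimated correlation) and 7 in IL-12Rβ2 cells (median log2 1.12, camera adjusted p = 1.19e-05, adjusted p = 0.0915 with an estimated correlation). So did inhibitory receptor genes, 5 of 10 (median log2 1.09, camera adjusted p = 0.00285, adjusted p = 0.0915 with an estimated correlation) and 5 (median log2 0.98, camera adjusted p = 0.00227, adjusted p = 0.0915 with an estimated correlation). With time matched and the cytokine on both sides, 7 follicular helper genes rose in IL-23R cells and 8 in IL-12Rβ2 cells. Of the inhibitory receptor genes, 5 rose in each line.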
